A study of Mus musculus with 2 samples.

How the data were processed

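Nuclear RNA was measured in droplets with the 10x Genomics 3' chemistry, version 3, and sequenced on an Illumina NovaSeq, per the labels' protocols. The samples were 1 male and 1 female library, each from nuclei of several pooled mice of the C57BL/6N strain, grouped by the sex given in the labels. Hypothalami were frozen and homogenised, and nuclei were gated on DAPI and on ZsGreen fluorescence before loading, per the labels' protocols. The number of mice in each pool was not given in the sources used here. Each deposited matrix held raw UMI counts per gene and barcode, written by Cell Ranger 6.1.2 per the file headers. Cell Ranger 6.1.2, Seurat 4.4.0 and the mouse builds GRCm38 and mm10 were named per the submitters' processing notes. How barcodes were called as nuclei, whether intronic reads were counted, the release of the reference and the use of strand in counting were not given in the sources used here, so genes that overlap a gene of the opposite strand are treated as uncertain. The deposited counts held no feature for ZsGreen or Cre, so the sorted signal itself was not analysed here.

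Positions and overlaps came from the GENCODE annotation of GRCm38. Of 32285 feature identifiers, 32158 were in it and 31436 had the same symbol. The files held 12442 barcodes, of which 382 male and 453 female ones with under 500 detected genes and a further 4 and 2 with over 5% mitochondrial UMIs were left out. Doublets were called per library with scrublet as implemented in scanpy. It marked 205 of 6363 female nuclei (3.22%), which were removed, and 0 of 5238 male ones. No doublets were thus removed from the male library, and they are taken to remain there. This left 11396 nuclei. CPM is the sum of a gene's UMIs over the nuclei of a class in a library, scaled by the sum of all UMIs of the same nuclei. Intervals are 95% exact Clopper-Pearson for shares and exact Poisson for sums, ratios between libraries have conditional binomial intervals, and 3 counts stand for the upper limit of a count of 0. At the depth of these libraries a single nucleus rarely shows a low transcript, so levels of receptors rest on sums.

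Counts were normalised to 10000 per nucleus, log-transformed and scaled to a maximum of 10, on genes seen in at least 3 nuclei. The 2000 most variable genes of each library were taken without mitochondrial genes and without the Y-linked and X-inactivation lists. Clusters came from 30 principal components, 15 neighbours and the Leiden method at resolution 1 on both libraries together, without batch integration, with seed 1. A cluster was named for a glial or vascular class when at least 3 of its markers exceeded the remaining nuclei by 3 times, with 10 CPM added to both, and for the class with the largest share of such markers where several qualified. Clusters whose median depth was below 0.333 of that of their own library stayed unnamed unless a marker of that class was among their top 10 genes. Cluster 9 stayed unnamed because all 6 astrocyte markers exceeded the rest but none was among its top 10 genes, although 5 of 6 oligodendrocyte markers also did and 2 of them were among the top 10. Of the others, a cluster with at least 3 neuronal markers was called MCH-like when its median Pmch count exceeded 2 times the glial median in each library, and other neuron otherwise. This multiple was set after seeing the data. Markers of particular neuron types were used to describe clusters and not to name them. To compare shares of nuclei with a UMI, each nucleus was thinned at random to 2000 UMIs and shallower nuclei were left out, with oligodendrocyte-like nuclei as the background or all glia where there were fewer than 50.

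MCH-like nuclei and other neurons were compared on counts summed per library and class, with the library in the model. The quasi-likelihood test of edgeR 4.0.16 was used with TMM scaling, its default expression filter and Benjamini-Hochberg adjusted p of 0.05 as the threshold. Standard errors are the absolute log2 fold over the square root of the F statistic. Values without 1 of the libraries are log2 ratios with no test. For MCH subclusters, each UMI was assigned at random to 1 of 2 parts, subclusters were made from the first with 20 components at resolution 0.5, and each subcluster with at least 20 nuclei in each library was tested against the remaining MCH-like nuclei in the second. Both parts come from the same nuclei, so nuclei divided along a gradient also differ in the second part. Between the sexes no test was made. Ratios were computed for genes with at least 200 counts in either library (12253 genes), and medians of lists, over members with at least 50 UMIs, were set against 10000 random lists matched on expression.

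Gene lists, cell type markers, tests and most alternatives were chosen before the data were examined. The lists were the orexin system, MCH subtype genes with Cartpt, fast transmitter genes, neuropeptide genes, feeding and metabolic receptors, insulin signalling, arousal and sleep transmitter receptors, ionotropic receptors, channels that set excitability, and sex steroid and prolactin signalling. They further held Y-linked genes, X-inactivation and X-escape genes, immediate early genes, clock genes, mitochondrially encoded genes as a sign of cytoplasmic RNA, heat shock and stress genes, and glial transcripts as a sign of free RNA. Some genes stand in several lists. Values of some genes that the rule below names are not reported here, although counts include them. Genes were named if they belonged to the orexin system or were Pmch, if they were among the 10 highest or 10 lowest folds of a comparison, or if they were among up to 4 members of a list with the largest folds. For the tests the 10 genes per side had to pass the threshold, go the same way in both libraries and reach a mean of 20 CPM. Predicted genes named Gm or Rik and ribosomal genes were counted but not named. Subclusters 4 to 7, the genes leading each cluster and the members of lists shown besides these 4 were chosen after their values were seen.

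Alternatives covered the gene minimum, doublets, clustering resolution, each library clustered alone, the depth of thinning, the expression filter, the model, the division of the UMIs, the scaling between libraries, equal weights for subclusters, and an MCH class made from the Pmch share of UMIs. DESeq2 1.42.0 replaced edgeR in another. Chosen after seeing the data were the removal of the highest 5% of doublet scores, of nuclei above 40000 UMIs, of male-library nuclei with Xist and no Y-linked UMI and of MCH-like clusters with under 3 MCH markers above other neurons, the naming of cluster 9 from its leading markers, and the subcluster values without 1 of the libraries. So was an MCH class made from Pmch UMIs above those of clusters with Gad2 over 5 or over 8 times the rest, of which the larger multiple was added when the smaller one took in cluster 8 (5.08 times).

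The tests were tried on simulated data drawn from the means, depths and fitted spread of the real sums, with groups fixed in advance. Far fewer genes were changed than were called in the data, and no clustering was simulated. The false calls below thus do not measure error that comes from classes made by clustering. For MCH-like nuclei against other neurons, with 192 changed among 16920 genes, edgeR recovered 75.8% of genes changed 2-fold and 93.8% of those changed 4-fold with 4 false calls, and DESeq2 52.6% and 85.6% with 0. For subcluster 1, with 195 changed among 14639 genes, edgeR recovered 80.2% and 97.0% with 7 false calls, and DESeq2 56.3% and 81.8% with 0. Calculations used R 4.3.3, limma 3.58.1, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.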

Results

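Gene expression was measured in single nuclei from hypothalami of mice in which MCH-Cre, a recombinase driven in neurons that make melanin-concentrating hormone (MCH), switched on the green fluorescent protein ZsGreen. Nuclei positive for ZsGreen and for the DNA dye DAPI were sorted, and several mice of a sex were pooled, giving 1 male and 1 female library of droplet 3' RNA with molecular identifiers (UMIs). The design names subtypes of MCH neurons as its aim, and the series title names orexin receptor 2 in these neurons, REM sleep and insulin sensitivity. The male library held 5624 barcodes and 33174364 UMIs, with a median of 3890 UMIs and 2158.5 genes per barcode and a range of 501 to 295670 UMIs. The female library held 6818 barcodes and 59418115 UMIs, with medians of 7734.5 UMIs and 3297 genes and a range of 500 to 59987 UMIs. Filters left 5238 male and 6158 female nuclei, with medians of 4545 and 8087.5 UMIs. With 1 library per sex there is no replicate check of any difference between the sexes, and the 95% intervals on shares (exact Clopper-Pearson) and on UMI sums (exact Poisson) cover counting error only.

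The first comparison asked which cells the sort had collected. MCH-like neurons, named from clusters rich in Pmch transcripts, made up 2364 of the male nuclei (45.1%, 43.8 to 46.5) and 4568 of the female nuclei (74.2%, 73.1 to 75.3). Other neurons made up 827 male nuclei (15.8%, 14.8 to 16.8) and 970 female nuclei (15.8%, 14.9 to 16.7). Glia and vascular cells made up 524 male nuclei (10.0%, 9.20 to 10.8) and 145 female nuclei (2.35%, 1.99 to 2.76). Among them were oligodendrocyte-like nuclei (190 male, 3.63%; 70 female, 1.14%), astrocyte-like nuclei (155 male, 2.96%; 36 female, 0.585%) and endothelial-like nuclei (100 male, 1.91%; 13 female, 0.211%). No cluster took the name of microglia, tanycytes or pericytes, although Rgs5, a pericyte gene, was among the leading genes of the endothelial-like cluster. The remaining 1523 male nuclei (29.1%, 27.8 to 30.3) and 475 female nuclei (7.71%, 7.06 to 8.41) lay in 2 shallow clusters. One, with a median depth of 1195.5 UMIs, was led by mt-Co3, Actb and Fth1, the other, cluster 9, with 1257, by Ttr, Mbp and Mobp, and both stayed unnamed. Cluster 9 held 526 male (10.04%, 9.24 to 10.9) and 64 female nuclei (1.04%, 0.801 to 1.33) with markers of astrocytes and oligodendrocytes, and named from its leading markers it would bring oligodendrocyte-like nuclei to 13.7% and 2.18% and glia to 20.05% and 3.39%. The sort and the depth gap between the libraries can set these shares. With a minimum of 1000 detected genes the MCH-like share was 56.5% in the male and 79.7% in the female library. The other male shares depended on the settings. With the 205 female doublet calls kept, male other neurons were at 27.6%, glia at 18.7%, oligodendrocyte-like nuclei at 12.2% and unnamed ones at 10.0%. No male nucleus was marked as a doublet, so these shares cover the same 5238 male nuclei, and only their clusters and names changed. With at least 200 genes these 4 male shares were 24.1%, 18.3%, 11.8% and 14.9%. With each library clustered alone female endothelial-like nuclei were at 4.34% and female glia at 6.11%.

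**Figure D1:**
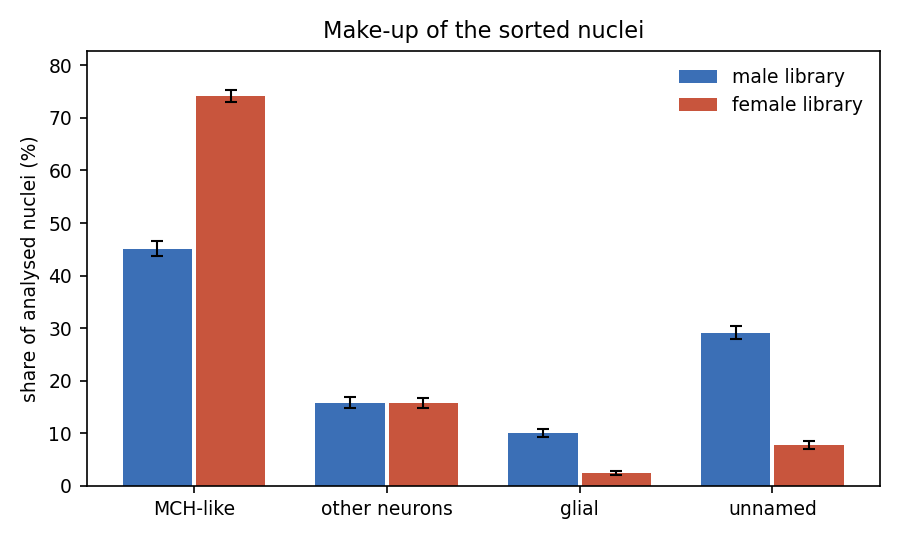
Share of analysed nuclei (%) in each class, with bars for the male and the female library and 95% exact binomial intervals as error bars. MCH-like nuclei held 45.1% of the male and 74.2% of the female library, and unnamed shallow nuclei 29.1% and 7.71%.

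Pmch encodes the precursor of MCH (ENSMUSG00000035383; GRCm38 chromosome 10, 88091072 to 88092375, plus strand). Its transcripts were in 99.98% of analysed male and 100% of analysed female nuclei. The median nucleus held 106 Pmch UMIs in the male and 101 in the female MCH-like class, against 14 and 21 in other neurons and 12 and 23 in glia. In the unnamed shallow cluster led by mt-Co3 it held 27 and 29, above other neurons and glia, at median depths of 1219 and 1147 UMIs. In cluster 9 it held 17 and 19. The 997 male and 411 female nuclei led by mt-Co3 stayed unnamed for their depth, before the Pmch rule was applied. Whether MCH nuclei are among them was not tested. Nuclei of the MCH-like clusters held a median of 4.96 to 11.6 times the glial level in the male and 3 to 6.26 times in the female library, and those of the other neuronal clusters 0.917 to 1.58 times and 0.739 to 1.09 times. The line between them, 2 times the glial median, was set after seeing the data and kept the 15.8% of each library called other neurons out of the MCH-like class. Of the MCH markers, clusters 4 (led by Tmem132c, Nrg1, Adcy2 and Reln) and 11 (led by Ror2, Gpr101 and Tmem163) had only Pmch and Parpbp above other neurons. Parpbp lies on the opposite strand over Pmch (chromosome 10, 88091432 to 88146941), so its counts are uncertain. These clusters held 498 male MCH-like nuclei (21.1%, 19.4 to 22.8) and 892 female ones (19.5%, 18.4 to 20.7). Without them the MCH-like share was 35.6% in the male and 59.7% in the female library.

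The next question was whether MCH nuclei carry transcripts of the orexin receptors. Transcripts of Hcrtr2, which encodes orexin receptor 2, were at a lower level in MCH-like nuclei than in the other sorted neurons. MCH-like nuclei held Hcrtr2 at 1.01 CPM (0.642 to 1.52; 23 UMIs) in the male and 1.65 (1.30 to 2.05; 79 UMIs) in the female library. Other neurons held it at 24.3 CPM (20.4 to 28.7; 137 UMIs) and 22.6 (19.1 to 26.5; 150 UMIs). Male glia held it at 4.72 CPM (2.16 to 8.96), but at 16.1 (11.9 to 21.3) with a minimum of 1000 detected genes. With MCH nuclei called from Pmch UMIs against clusters with Gad2 over 8 times the rest, male MCH-like nuclei held it at 2.70 CPM (2.09 to 3.44), and against clusters with Gad2 over 5 times, other neurons held it at 9.99 (8.41 to 11.8) in the male and 13.5 (11.5 to 15.7) in the female library. Hcrtr1, which encodes orexin receptor 1, was at a like level in both classes, with 7.83 CPM (6.72 to 9.07) in male and 6.92 (6.19 to 7.70) in female MCH-like nuclei, against 8.68 (6.42 to 11.5) and 7.39 (5.46 to 9.76) in other neurons. Hcrtr2 (ENSMUSG00000032360) lies on chromosome 9 at 76225880 to 76323856, minus strand, and overlaps a gene of the opposite strand, whereas Hcrtr1 (ENSMUSG00000028778; chromosome 4, 130130217 to 130139359, minus strand) overlaps none.

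With every nucleus thinned to 2000 UMIs, 4 of 2299 male MCH-like nuclei had a Hcrtr2 UMI (0.174%, 0.0474 to 0.445) and 11 of 4549 female ones (0.242%, 0.121 to 0.432). The background was 1 of 81 male oligodendrocyte-like nuclei (1.23%, 0.0313 to 6.69) and 0 of 80 female glial nuclei, which allows up to 3.75%, and in all male glia it was 5 of 294 (1.70%, 0.554 to 3.92). The MCH-like shares of Hcrtr2 were thus not above the background. So few background nuclei cannot tell a low level of expression from free RNA, and the shares are read as neither. In other neurons the shares were 22 of 726 in the male (3.03%, 1.91 to 4.55) and 33 of 940 in the female library (3.51%, 2.43 to 4.90). The male interval overlapped that of oligodendrocyte-like nuclei and of glia and the female share lay below the glial limit, so these shares alone do not separate other neurons from the background. Hcrtr1 was seen in 38 male (1.65%, 1.17 to 2.26) and 61 female MCH-like nuclei (1.34%, 1.03 to 1.72), in 1.24% (0.568 to 2.34) and 1.81% (1.06 to 2.88) of other neurons, in 0 of 81 male oligodendrocyte-like nuclei and 0 of 80 female glial nuclei, which allow up to 3.70% and 3.75%, and in 1 of 294 male glial nuclei (0.340%, 0.00861 to 1.88). These shares too are not separated from the background, which held too few nuclei to show a difference of this size. With cluster 9 counted as oligodendrocyte-like the male background was 1 of 221 nuclei for Hcrtr2 (0.452%, 0.0115 to 2.50) and 0 of 221 for Hcrtr1, which allows up to 1.36%. Thinning left out 65 male and 19 female MCH-like nuclei, 101 and 30 other neurons, and 230 and 65 glia, whose median depths before thinning were 8879 and 9366, 5379 and 6163.5, and 2256 and 2095 UMIs. Without thinning, Hcrtr2 was in 0.804% of male and 1.29% of female MCH-like nuclei, in 10.0% of other neurons of each library and in 1.53% of male glia, and Hcrtr1 in 6.68% and 6.52% of MCH-like nuclei and 5.44% and 4.33% of other neurons.

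**Figure D2:**
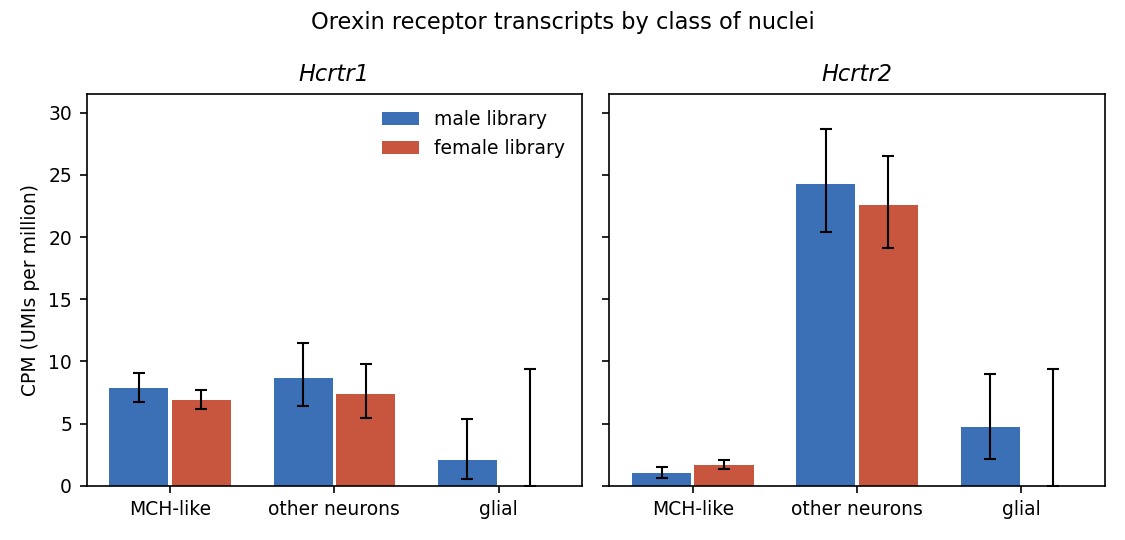
Summed CPM of Hcrtr1 and Hcrtr2 (vertical axis) in MCH-like nuclei, other neurons and glia of the male and female libraries, with 95% exact Poisson intervals as error bars. Hcrtr2 lay at 1.01 and 1.65 in MCH-like nuclei and at 24.3 and 22.6 in other neurons, while Hcrtr1 lay between 6.92 and 8.68 in both.

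Within the MCH-like class, Hcrtr2 was highest in cluster 1, led by Sulf1, Adamtsl1 and Ntn1, with 3.35 CPM (1.78 to 5.73) in the male and 4.85 (3.48 to 6.58) in the female library. Both intervals overlapped that of male glia, but glial nuclei were far shallower, so their CPM does not measure free RNA per nucleus. Hcrtr1 was highest in cluster 11, with 21 (14.6 to 29.2) and 20.6 (15.4 to 27.0). Among other neurons, cluster 8 (Meis2, Foxp2, Synpr), which held the largest part of the class in the male library, had Hcrtr2 at 28.1 CPM (22.5 to 34.7) and 25.8 (17.6 to 36.4). Cluster 10 (Pcdh15, Chrm3, Glra3), which held the largest part in the female library, had 22.5 (14.6 to 33.2) and 30.7 (24.2 to 38.4). Cluster 12 (Otx2os1, Il1rapl2, Lgr5) had less Hcrtr2, 12.7 (5.48 to 25) and 6.35 (2.55 to 13.1), and more Hcrtr1, 17.5 (8.72 to 31.2) and 24.5 (16.2 to 35.7). Hcrt, the orexin precursor, was at 20.9 (19.1 to 22.9) and 14.6 (13.6 to 15.7) CPM in MCH-like nuclei, 109 (100.4 to 118) and 24.6 (20.9 to 28.6) in other neurons, and 38.3 and 132 in glia, a class that does not make it. Mchr1, the MCH receptor gene, was low in MCH-like nuclei at 2.11 (1.56 to 2.80) and 1.73 (1.38 to 2.14) CPM and in other neurons at 2.30 and 2.41.

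Counts summed over the MCH-like nuclei and over the other neurons of each library were then compared to find what sets MCH neurons apart from the neurons sorted with them. MCH-like nuclei were higher in A2m, a protease inhibitor, by a log2 fold of 3.84 ± 0.15 (SE), in Tacr3, the neurokinin B receptor, by 3.63 ± 0.25 and in Htr1d, a serotonin receptor, by 3.46 ± 0.16. They were lower in Otx2os1, a long noncoding RNA (-7.82 ± 0.15), in Ldb2, a cofactor of LIM-domain transcription factors (-6.72 ± 0.12), and in Hcrtr2 (-3.95 ± 0.22). Each of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p of 3.15e-10 for A2m, 9.01e-08 for Tacr3, 3.23e-13 for Otx2os1, 2.41e-13 for Ldb2 and 1.02e-08 for Hcrtr2. Of 17418 genes tested, 3080 were higher and 3594 lower in MCH-like nuclei in the same test. Each direction held in both libraries for the genes named here, which the naming rule required of those named by fold. The other genes highest by fold were Mup6 (4.0 ± 0.16), Ccbe1 (3.53), Tnfaip8 (3.35), Dab2 (3.17), Dpyd (3.08), Palmd (2.94) and Rspo3 (2.92). The lowest also included Pcdh15 (-6.04), the transcription factor genes Ebf1 (-5.92) and Meis2 (-5.65), Tafa1 (-5.81), the kainate receptor gene Grik3 (-5.64), Adamts3 (-5.44), Arpp21 (-5.26) and Il1rapl2 (-5.20). A2m lies on chromosome 6 at 121635376 to 121679227, Tacr3 on chromosome 3 at 134829007 to 134934579, Ldb2 on chromosome 5 at 44472132 to 44799680 and Otx2os1 on chromosome 14 at 48668708 to 48870683, where it overlaps Otx2 on the other strand. Mup6 belongs to a family of near-identical genes, so its value is uncertain, as are those of Ldb2 and Otx2os1, which have overlapping partners.

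The fold of Tacr3 was 4.51 without the male and 2.74 without the female library, and without the female library Hcrtr2 was at -4.58, A2m at 3.22, Palmd at 2.33 and Grik3 at -6.32. DESeq2 called 1228 genes higher and 1769 lower, and with nuclei thinned to 2000 UMIs the counts were 1891 and 2106. The test rested on 4 sums from 2 libraries with 1 residual degree of freedom, on classes made from the same counts. Its p-values thus rest on counting error and on a spread shared across genes of these 2 pools, and do not measure the spread between mice.

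Fast transmitter genes differed between the summed classes, but other neurons mixed GABAergic and glutamatergic clusters. Gad2 and Slc32a1 were far lower in clusters 10 and 14 than in clusters 12 and 16, so their folds depend on that mix. Gad2, a GABA-synthesis enzyme, and Slc32a1, the vesicular GABA transporter, were lower in MCH-like nuclei, at -3.72 ± 0.09 and -4.39 ± 0.19 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 2.41e-12 and 9.73e-10), and Slc17a6, a vesicular glutamate transporter, was lower at -0.52 ± 0.08. Gad1 was higher by 0.56 ± 0.08. Of the 7 members tested 1 was higher, 5 were lower and 1 did not pass, Slc17a8 (0.42 ± 0.52). In the list of MCH subtype genes with Cartpt, 3 of 7 were higher and 4 lower. Cartpt, a peptide precursor (chromosome 13, 99898489 to 99901091), was higher by 1.66 ± 0.09 and Nptx1 by 1.83 ± 0.11, besides Tacr3, while Tacr1 (-2.73 ± 0.22), Cck (-1.94 ± 0.25), Scg2 (-1.36 ± 0.09) and Cnr1 (-1.33 ± 0.20) were lower. Cck stood at -1.29 without the male and -2.66 without the female library. Of 23 neuropeptide genes tested, 3 were higher, 14 lower and 6 did not pass, or 4 higher and 15 lower adjusted over the list alone. Nucb2 was higher by 1.85 ± 0.10, and so was Pmch (1.84 ± 0.10), which defines the class. Nts (-4.0 ± 0.26), Sst (-3.70 ± 0.16), Tac2 (-3.39 ± 0.34) and Trh (-3.22 ± 0.67) were lower. All 8 mitochondrial genes, 8 of 11 glial transcripts and 5 of 7 stress genes, signs of cytoplasmic and free RNA and of stress, were lower in the same comparison. Without the female library Tac2 was at -4.01 and Trh at -5.42, and without the male library Trh was at -1.53. Trh was also at 0.49 with MCH nuclei called from Pmch UMIs against clusters with Gad2 over 5 times the rest.

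In the orexin list 2 of 3 genes were lower, Hcrtr2 and Hcrt, and Hcrtr1 did not pass (0.00 ± 0.19; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.988). Hcrt was lower at -1.53 ± 0.25, but stood at -0.75 without the male library, at -2.38 without the female library and at 0.13 with MCH nuclei called from Pmch UMIs against clusters with Gad2 over 8 times the rest, and did not pass with DESeq2 (-1.44). Receptors for feeding and metabolic signals were mostly lower: 13 of 21 tested were lower, 4 were higher and 4 did not pass. The mitochondrial genes (8 of 8) and glial transcripts (8 of 11) were lower too. Galr1 (-4.11 ± 0.58), Calcr (-3.97 ± 0.49), Npy5r (-3.88 ± 0.36) and Crhr1 (-3.75 ± 0.28) were lowest. Calcr was at -5.29 without the female library and -3.34 without the male library. Npy2r (2.31 ± 0.21), Tacr3, Igf1r (0.44 ± 0.08) and Insr (0.23 ± 0.08), the insulin receptor gene, were higher. Mchr1 (-0.19 ± 0.36) did not pass. Of 25 insulin signalling genes tested, 9 were higher, 2 lower and 14 did not pass. Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, was higher by 1.74 ± 0.11 and Foxo6 by 1.63 ± 0.20. Kcnj11, the pore subunit of the ATP-sensitive potassium channel, was lower at -1.77 ± 0.31 and Foxo3 at -0.62 ± 0.12.

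Receptors for arousal transmitters were lower in 18 of 29 cases, higher in 4 and did not pass in 7, and the mitochondrial genes (8 of 8) and glial transcripts (8 of 11) were lower with them and with the ionotropic receptors and channels that follow. The serotonin receptor gene Htr4 (-4.45 ± 0.14), the dopamine receptor genes Drd2 (-4.35 ± 0.49) and Drd1 (-2.74 ± 0.55) and the muscarinic receptor gene Chrm3 (-4.24 ± 0.09) were lower. The adrenergic receptor gene Adra2a (1.29 ± 0.19), the histamine receptor genes Hrh3 (1.09 ± 0.14) and Hrh1 (0.31 ± 0.12) and Htr2c (0.84 ± 0.10) were higher. Drd2 was at -3.27 without the male and -5.56 without the female library, and Drd1 at -1.98 and -3.67. Of 20 ionotropic receptor genes 6 were higher, 10 lower and 4 did not pass, with Glra3, a glycine receptor subunit, at -3.99 ± 0.11, Gabra3 at -1.40 ± 0.10, Gabra5 at -1.36 ± 0.10 and Gabra2 at 1.23 ± 0.09. Of 24 channel genes that set excitability 3 were higher, 11 lower and 10 did not pass, or 4 higher and 12 lower adjusted over the list alone. Kcnk9 (-4.11 ± 0.25), Kcnj3 (-2.05 ± 0.10) and Trpc6 (-1.29 ± 0.12) were lower and Slc8a1, the sodium-calcium exchanger gene, was higher (0.77 ± 0.10). Among 8 genes of sex steroid and prolactin signalling tested, 2 were lower and 6 did not pass. Greb1 was lower at -1.50 ± 0.45 and did not pass with DESeq2 (-1.51).

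Immediate early genes were lower in 4 of 8 cases and did not pass in 4, or lower in 5 adjusted over the list alone. Fos was at -2.50 ± 0.40, Egr1 at -1.84 ± 0.26 and Jun at -1.35 ± 0.18. Without the male library Fos was at -2.02 and without the female library at -3.48. Of 15 clock genes 11 were lower and 4 did not pass, or 12 lower adjusted over the list alone, with Npas2 at -2.43 ± 0.15, Per2 at -1.32 ± 0.19 and Per1 at -1.16 ± 0.18. All 8 mitochondrially encoded genes, a sign of cytoplasmic RNA, were lower in MCH-like nuclei, with mt-Atp6 at -1.27 ± 0.16 and mt-Nd4 at -1.21 ± 0.20, both of which did not pass with the library left out of the model (-1.38 and -1.37). Of 7 heat shock and stress genes 5 were lower and 2 did not pass, with Hspa8 at -1.0 ± 0.09 and Hsp90aa1 at -0.89 ± 0.08, which stood at -0.14 and -0.10 and did not pass with MCH nuclei called from Pmch UMIs against clusters with Gad2 over 5 times the rest. Glial transcripts, a sign of free RNA, were lower in 8 of 11 cases and did not pass in 3, with the astrocyte gene Slc1a3 at -3.07 ± 0.27 and the myelin gene Mbp at -1.48 ± 0.14. Of the Y-linked genes 3 of 4 tested were higher, Eif2s3y (0.50 ± 0.13), Kdm5d (0.50 ± 0.14) and Uty (0.43 ± 0.11), and Ddx3y (0.15) did not pass. These values came from the male library, Uty and Kdm5d did not pass with DESeq2, and Eif2s3y was at -0.98 there. Kdm5d was at -1.86 without the male library. Of 8 genes of X inactivation and escape 1 was higher, 2 were lower and 5 did not pass, or 1 higher and 3 lower adjusted over the list alone, with Ftx at -0.40 ± 0.10, Ddx3x at -0.36 ± 0.11 and Kdm5c at 0.30 ± 0.08, the last of which did not pass with DESeq2 (0.30), nor did Ddx3x (-0.37). In every list without a second count, the counts adjusted over the list alone were identical.

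The design's stated aim was a division of MCH neurons into molecular subtypes. Clusters were made from one random part of each MCH-like nucleus's UMIs and all values were read from the rest. This gave 7 subclusters. Cartpt, Tacr3 and Nptx1 were high in subclusters 3 and 4 and low in 1 and 2, whereas the opioid receptor gene Oprm1 and the adrenergic receptor gene Adra1a were high in 1 and 2 and low in 3 and 4. Subclusters 1 and 2 were low in Cartpt, with 54.6 and 68.3 CPM in the male and 70.4 and 65.9 in the female library, and high in Oprm1, with 63.8 and 67.9, and 69.4 and 74.8. Subclusters 3 and 4 were high in Cartpt, with 1293 and 960 in the male and 992 and 783 in the female library, and low in Oprm1, with 4.21 and 5.04, and 2.54 and 2.41. Of subcluster 1, 59.0% of male (54.4 to 63.5) and 59.0% of female nuclei (55.7 to 62.3), and of subcluster 2, 43.5% (39.1 to 48.0) and 46.0% (42.5 to 49.5), lay in clusters 4 and 11. There only Pmch and Parpbp of the MCH markers exceeded other neurons, so their MCH name rests on Pmch and is less certain. The markers Tacr3, Cartpt and Nptx1 are also in the Cartpt subtype list, so they cannot decide the name of nuclei low in Cartpt. The median Pmch count of clusters 4 and 11 was 120.5 and 110.5 UMIs in the male library and 118 and 122 in the female one. The whole MCH-like class held 106 and 101. Subcluster 5 had Tacr3 at 295 and 288 but little Cartpt (180 and 134), and subcluster 6 had both Cartpt (1009 and 696) and Tacr3 (232 and 274).

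Subcluster 1 held 473 male (20.01%, 18.4 to 21.7) and 884 female nuclei (19.4%, 18.2 to 20.5), subcluster 2 held 492 (20.8%, 19.2 to 22.5) and 804 (17.6%, 16.5 to 18.7), and subcluster 3 held 398 (16.8%) and 788 (17.3%). Subcluster 4 held 354 male (15%, 13.6 to 16.5) and 830 female nuclei (18.2%, 17.1 to 19.3), and subclusters 5 and 6 held 338 and 278 male nuclei (14.3% and 11.8%) and 647 and 548 female nuclei (14.2% and 12.0%). The intervals of the libraries were apart for subclusters 2 and 4, without a test. Subcluster 7 held 31 male (1.31%, 0.893 to 1.86) and 67 female nuclei (1.47%, 1.14 to 1.86). The number of subclusters was 6 at a lower resolution, 11 at a higher one and 6 with a second random division of the UMIs. The overlap (Jaccard index) of each subcluster with its best partner in the second division was 0.570, 0.463, 0.392, 0.588, 0.753 and 0.38 for subclusters 1 to 6 and 0.0515 for subcluster 7, which had no counterpart there. Subclusters 3 and 6 had the same partner in the second division and at the lower resolution, so they were not told apart there.

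**Figure D3:**
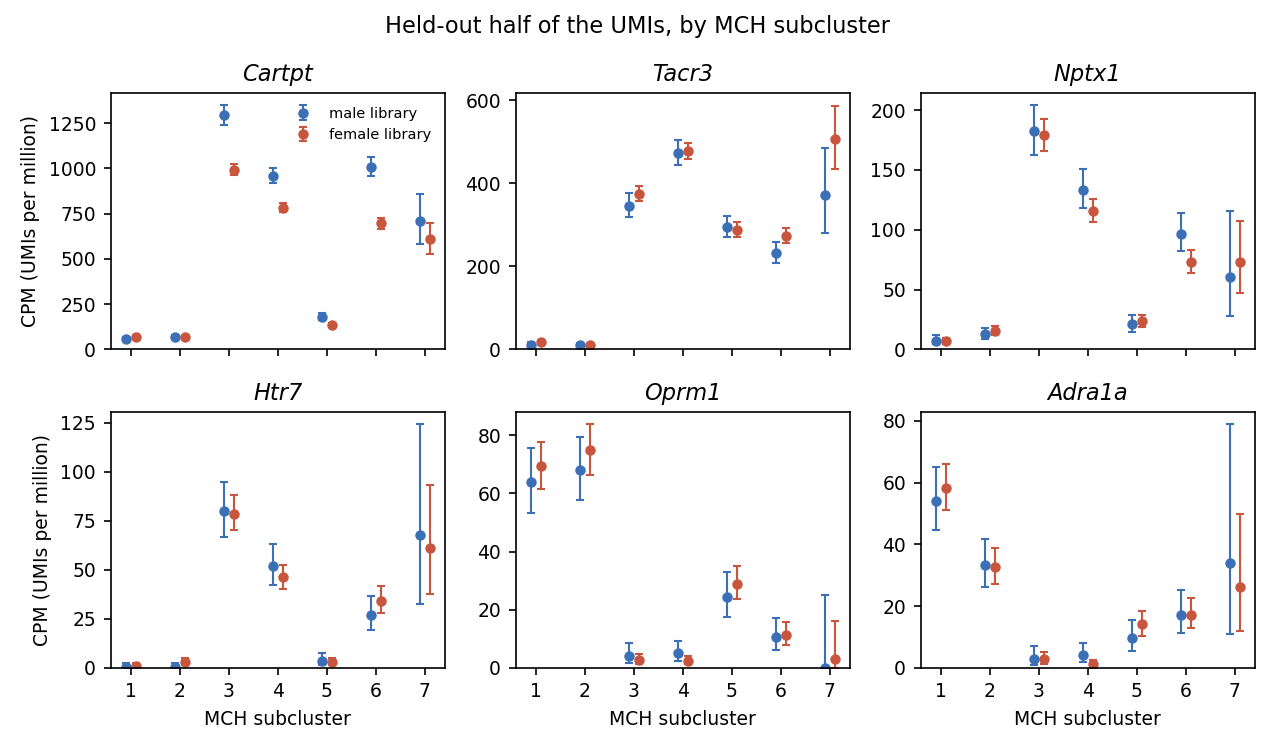
CPM (vertical axis) of Cartpt, Tacr3, Nptx1, Htr7, Oprm1 and Adra1a in MCH subclusters 1 to 7 (horizontal axis) of the male and female libraries, from the UMIs not used for clustering, with 95% exact Poisson intervals as error bars. Subclusters 1 and 2 had Oprm1 at 63.8 to 74.8 and Cartpt at 54.6 to 70.4, and subclusters 3 and 4 had Oprm1 at 2.41 to 5.04 and Cartpt at 783 to 1293.

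Subcluster 1, compared with the remaining MCH-like nuclei, was high in Adcy8, an adenylyl cyclase gene (2.67 ± 0.06), in the cadherin gene Cdh20 (2.57 ± 0.06), in Reln, which encodes reelin (2.22 ± 0.06), and in Adra1a (2.02 ± 0.12). It was low in the receptor tyrosine kinase gene Alk (-6.78 ± 0.07), in Ntn1, which encodes netrin (-6.1 ± 0.26), in Sulf1 (-5.24 ± 0.25) and in Tacr3 (-4.27 ± 0.09). Of 14899 genes tested 1413 were higher and 1483 lower, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.52e-63 for Adra1a and 2.60e-117 for Ntn1. Both went the same way in both libraries, as the naming rule required. Plch1 (2.48, and 1.37 at the higher resolution), Rasgef1b (2.31, and 1.02), Tll1 (2.27) and Zfhx3 (1.99) were also among the highest, and Adarb2 (-5.25), Adamtsl1 (-5.23), Kcnq5 (-4.42), Unc5d (-4.20), Ccbe1 (-4.06) and Sema3c (-3.96) among the lowest. Nrg1, which encodes neuregulin, and Tmem132c were higher by 2.65 ± 0.04 and 2.40 but only by 0.13 and 0.16, and not past the test, with the second division of the UMIs. Without the female library Ntn1, with 3 UMIs in the male subcluster, was at -5.02 (-7.30 to -3.46) and Adarb2 at -4.46, and without the male library Ntn1, with 2, was at -6.92 (-9.97 to -5.06). DESeq2 called 391 genes higher and 561 lower. Alk lies on chromosome 17 at 71868972 to 72604627, Nrg1 on chromosome 8 at 31814551 to 32884029, and Adcy8 on chromosome 15 at 64697084 to 64922296, and each overlaps a gene of the other strand and is uncertain for that reason.

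Of the subtype list, 1 of 7 members was higher in subcluster 1, Scg2 (1.61 ± 0.08), 4 were lower, among them Nptx1 (-3.66 ± 0.15) and Cartpt (-3.22 ± 0.06), and 2 did not pass. Of 22 arousal receptors tested 10 were higher, 5 lower (6 adjusted over the list alone) and 7 did not pass. Chrna7 (1.82) and Htr2a (1.68) were higher, while Htr7, a serotonin receptor gene, was lower at -5.41 ± 0.30 and Hrh3 at -2.25 ± 0.19. Insulin signalling genes were higher in 3 of 25 cases, lower in 5 and did not pass in 17, with Foxo1, a transcription factor that insulin signalling inhibits, at -3.56 ± 0.29 and Pik3r1 at -0.96. Of 12 feeding receptors 1 was higher, Ntsr1, a neurotensin receptor gene (3.47 ± 0.29), 4 were lower, with Npy1r (-2.57) not past DESeq2, and 7 did not pass. Ionotropic receptors were higher in 9 of 20 cases, lower in 7 (8 adjusted over the list alone) and did not pass in 4, with Grik1 at 0.95 and Glra2 at -1.93. Glra3 was higher by 2.33 ± 0.23 but stood at -0.41 at the higher resolution. Of 24 channel genes 9 were higher, 4 were lower, among them Kcnq5, and 11 did not pass. Sex steroid genes were lower in 3 of 7 cases (4 adjusted over the list alone) and did not pass in 4, with the estrogen receptor gene Esr2 at -3.88 ± 0.62 and the prolactin receptor gene Prlr at -1.07, which stood at -2.14 and -2.15 with the second division. Without the female library Htr7, with 1 UMI in the male subcluster, was at -6.02 (-11.3 to -3.53), and Npy1r, with 0 UMIs there, was at -1.63 (-3.97 to 0.0070) without the male library.

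In the orexin list of subcluster 1, Hcrt was higher by 0.71 ± 0.15, not past DESeq2, and Hcrtr1 did not pass. Fast transmitter genes were lower in 2 of 5 cases and did not pass in 3 (1 higher and 2 lower adjusted over the list alone), with Gad2 at -1.53 ± 0.27, and at -0.38 and not past the test with the second division. Neuropeptide genes were higher in 2 of 16 cases, lower in 2 and did not pass in 12, with Nucb2 at -1.39 and Pmch at 0.40. Clock genes were higher in 1 of 15 cases, lower in 3 and did not pass in 11, with Npas2 at -3.49 ± 0.39, or -2.83 (-5.14 to -1.24; 3 UMIs) without the female library, and Rorb at -1.69. Jun, the 1 immediate early gene of 6 past the test, was higher by 1.06 ± 0.25 and did not pass with DESeq2. Mitochondrial genes (1 of 8 higher), stress genes (3 of 6 higher), glial transcripts (1 higher and 1 lower of 6), X-linked genes (2 higher and 2 lower of 8) and Y-linked genes (0 of 4) followed, with mt-Nd2 at 0.87, Hspa5 at 0.42, Mobp at 0.77, Slc1a2 at -0.79 and Xist at -0.66. Of these, all but Xist did not pass with DESeq2.

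Subcluster 2 was high in Kcnip1, which encodes a subunit of A-type potassium channels (4.76 ± 0.10), in Nell1 (3.20 ± 0.10) and in Gmnc (2.92 ± 0.16). It was low in Tacr3 (-4.86 ± 0.10, and -2.91 with the second division), A2m (-4.26 ± 0.12) and the transcription factor gene Lef1 (-3.84, and -3.22 without the female library). Of 14870 genes tested 1419 were higher and 1443 lower, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.18e-75 for Gmnc, and these genes went the same way in both libraries. Cdh13 (2.22), Ano3 (2.22), Flrt2 (2.20), Edil3 (2.05) and Car8 (2.02) were higher, and Kctd8 (-3.92), Sulf1 (-3.83), Alk (-3.57), Tspan9 (-3.18), Cartpt (-3.17), Rreb1 (-3.08) and Gfra1 (-2.77) lower. Hcrtr1 was higher by 1.18 ± 0.21, with 15.1 CPM in the male and 12.4 in the female library (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.83e-07). It did not pass with DESeq2 and was at -0.11 with the second division of the UMIs. Ror2 was higher by 2.22 ± 0.15 but stood at -0.46 with the second division and at -0.0061 at the higher resolution. With the second division 731 genes were higher and 929 lower, Flrt2 was at 1.23, Alk at -2.30 and Gfra1 at -1.80, and with DESeq2 391 genes were higher and 505 lower. Kcnip1 lies on chromosome 11 at 33629339 to 33993152, overlapping Kcnmb1 on the other strand, which leaves its value uncertain.

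Of the subtype list 1 of 7 was higher in subcluster 2, Scg2 (0.90), 5 were lower, with Nptx1 at -2.58 and Cnr1 at -1.79, and 1 did not pass. Of 24 arousal receptors 7 were higher (9 adjusted over the list alone), 9 lower and 8 did not pass, with Htr7 at -4.14 ± 0.24, Oprk1 at -1.98 and Htr4 at 1.90. The dopamine receptor gene Drd5 was higher by 3.29 ± 0.66 and did not pass with DESeq2. Of 12 feeding receptors 1 was higher, Npy1r (2.65 ± 0.34), 6 were lower, with Npy2r at -1.70 (-1.04 with the second division), and 5 did not pass. Insulin signalling genes were higher in 2 of 25 cases, lower in 6 and did not pass in 17, with Foxo1 at -1.53 ± 0.20, which stood at -0.98 with the second division, and Pik3r1 at -1.16. Ionotropic receptors were higher in 8 of 20 cases, lower in 8 (9 adjusted over the list alone) and did not pass in 4, with Gabrg3 at -0.91 and Grik1 at 0.83. Of 23 channel genes 9 were higher (10 adjusted over the list alone), 6 lower (7) and 8 did not pass, with Kcnj3 at 1.06 ± 0.07 and Kcnq5 at -1.76. Of 7 sex steroid genes 2 were higher (3 adjusted over the list alone), with the estrogen receptor gene Esr1 at 1.02 ± 0.16, 3 were lower and 2 did not pass. Without the female library Cnr1 and Htr7, each with 1 UMI in the male subcluster, were at -3.94 (-9.27 to -1.41) and -6.23 (-11.5 to -3.74). Of 15 clock genes 1 was higher, 3 were lower, with Rorb at -1.54 (-0.93 with the second division), and 11 did not pass.

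Among the other lists of subcluster 2, the fast transmitter genes were higher in 2 of 4 cases, lower in 1 and did not pass in 1. Neuropeptide genes were higher in 2 of 17 cases, lower in 3 and did not pass in 12, with Nucb2 at -1.36 and with Ghrh at 1.1 ± 0.42 but at -0.45 with the second division. In the orexin list Hcrtr1 was higher, Hcrtr2 was lower (-1.90 ± 0.73; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0459) with 0 UMIs in the male and 3 in the female subcluster and not past DESeq2, and 1 gene did not pass. None of the 8 mitochondrial and 4 Y-linked genes passed, and 1 of 6 stress genes, 1 of 6 glial transcripts, 1 of 6 immediate early genes and 3 of 8 X-linked genes did. The glial transcript was Slc1a2, at 0.64 and at -0.11 with the second division.

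Subcluster 3 was high in Luzp2 (3.23 ± 0.13), in Mylk, a myosin kinase gene (3.11 ± 0.12), in Adamtsl1 (2.99 ± 0.05) and in Htr7 (2.10 ± 0.11). It was low in the adenylyl cyclase genes Adcy2 (-6.12 ± 0.12) and Adcy8 (-5.31 ± 0.16) and in Oprm1 (-3.61 ± 0.23). Of 15044 genes tested 1573 were higher and 1442 lower, with edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 3.04e-95 for Adamtsl1 and 5.77e-83 for Adcy2, and these genes went the same way in both libraries. The collagen gene Col11a1 (3.06), Rbm47 (2.75), Ntn1 (2.54), Has2os (2.41), Lmo2 (2.38), Sulf1 (2.34) and Kcnq5 (2.22) were higher, and Flrt2 (-5.25), Hs3st2 (-5.06), Col18a1 (-4.37), Cdh20 (-4.30), Kcnip1 (-4.30), Nrg1 (-3.96), Reln (-3.80) and Erbb4, a neuregulin receptor gene (-3.78), lower. With the second division Luzp2 was at 2.21, Mylk at 1.97, Rbm47 at 1.35 and Hs3st2 at -3.66, at the lower resolution Sulf1 was at 3.6, and without the female library Luzp2 was at 2.41, Adcy2 at -5.52, Flrt2 at -3.89 and Kcnip1 at -3.53. Without the male library Flrt2, with 2 UMIs in the female subcluster, was at -6.75 (-9.79 to -4.89), and DESeq2 called 512 genes higher and 518 lower. Adamtsl1 lies on chromosome 4 at 85514172 to 86428385 and Adcy2 on chromosome 13 at 68620043 to 68999541, both with overlapping genes of the other strand that leave their values uncertain.

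Of the subtype list 3 of 7 were higher in subcluster 3, Nptx1 (1.82 ± 0.07), Cartpt (1.5 ± 0.04) and Tacr3 (0.74 ± 0.05), 1 was lower, Scg2 (-2.0 ± 0.14), and 3 did not pass. Of 22 arousal receptors 4 were higher, 6 lower and 12 did not pass, with Adra1a at -3.12 ± 0.25 and Chrm3 at 1.44. Adra1a was at -1.16 with the second division and at -1.40 at the lower resolution. Of 25 insulin signalling genes 5 were higher, among them Foxo1 (2.00 ± 0.13) and Pik3r1 (0.87), 1 was lower and 19 did not pass. Ionotropic receptors were higher in 3 of 20 cases (4 adjusted over the list alone), lower in 13 and did not pass in 4, with Glra2 at 1.70, Grik1 at -1.23 and Gria3 at -0.99. Of 23 channel genes 4 were higher, 10 lower (11 adjusted over the list alone) and 9 did not pass. Kcnj3 was at -2.41 ± 0.14 but at -1.82 without the female library and at 0.10 with the second division. Of 7 sex steroid genes 2 were higher, with Esr2 at 1.32 and not past DESeq2, 1 was lower and 4 did not pass. Clock genes were higher in 4 of 15 cases and did not pass in 11, with Npas2 at 1.71 ± 0.18 and Rorb at 1.13, which stood at 3.33 with the second division and 3.16 at the lower resolution.

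Among the other lists of subcluster 3, fast transmitter genes were higher in 2 of 5 cases (3 adjusted over the list alone) and did not pass in 3, but Gad2 (1.08 ± 0.19) stood at -0.12 with the second division. Neuropeptide genes were higher in 2 of 17 cases, lower in 4 and did not pass in 11, with Nucb2 at 1.05 and Pmch at -0.41. Of 13 feeding receptors 2 were higher, with Igf1r at 0.54, 1 was lower and 10 did not pass. The lower one, Ntsr1, had 0 UMIs in subcluster 3 of either library, which allows 1.80 CPM in the male and 0.762 in the female library. Hcrt was lower at -0.76 ± 0.19 and not past DESeq2, and the 2 orexin receptors did not pass. Of 6 immediate early genes 1 was higher (2 adjusted over the list alone) and 1 lower, of 8 X-linked genes 1 was higher and 1 lower (2), of 6 stress genes 3 were lower, of 5 glial transcripts 1 was higher, and none of the 8 mitochondrial and 4 Y-linked genes passed. In all subcluster tests the 2 libraries gave 1 residual degree of freedom and the spread was shared across genes. That spread was small, with a median dispersion of 0.00071 for subcluster 1. These p-values thus rest largely on UMI counting error within the same 2 pools and do not measure the spread between mice.

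Subclusters 4 to 7 had 1300, 729, 722 and 176 genes higher and 1315, 893, 713 and 239 lower. Subcluster 4, led by A2m and Sphkap, was higher in Tacr3 (1.49 ± 0.05), Npy2r (1.49) and Prlr (1.26) and lower in Oprm1 (-3.51 ± 0.21, and -2.90 without the female library). Subcluster 5, led by the secretin receptor gene Sctr, was lower in Htr7 (-3.33 ± 0.24) and in Hcrtr1 (-2.76 ± 0.44; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 7.09e-07), the latter at -3.92 (-9.24 to -1.40; 1 UMI) without the female library. Subcluster 6, led by Adarb2 and Csmd1, was higher in Rorb (2.56 ± 0.13), Htr1b (2.45) and Hcrtr2 (1.81 ± 0.48; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00294). Hcrtr2 was at 2.70 there without the female library. Its Hcrtr2 level of 4.61 CPM (1.85 to 9.50) in the male and 3.95 (2.04 to 6.91) in the female library lay within the interval of male glia. Glial nuclei were far shallower, so this CPM does not compare free RNA per nucleus and decides nothing about this level. Subcluster 7, led by Il1rapl2 and Sim1, was higher in Gad2 (3.6 ± 0.34), Chrm3 (3.05 ± 0.28) and Adcyap1 (3.79) and lower in Pmch (-0.79). Its 10 leading genes held Gad2, Il1rapl2 and Chrm3, genes higher in other neurons, so it carries no name as an MCH subtype and its place in the class is doubtful. Of the 7 subclusters, only subcluster 4 had an MCH marker, Tacr3, among its 10 leading genes.

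The female and male libraries were then set side by side within MCH-like nuclei. Xist, the RNA that silences an X chromosome (X, 103460366 to 103483254), was at 633 CPM in the female and 37.1 in the male library, a log2 ratio of 4.10 (4.00 to 4.20), or 6.33 without the 82 male nuclei that held at least 3 Xist UMIs and no Y-linked UMI. Its antisense partner Tsix, which overlaps it, was at a ratio of 4.57 (4.32 to 4.82). The Y-linked Uty, Kdm5d and Ddx3y had 2 UMIs each in female MCH-like nuclei against 2841, 1442 and 945 in male ones, at ratios of -11.55 (-14.60 to -9.70), -10.57 (-13.62 to -8.72) and -9.96 (-13.01 to -8.11). Eif2s3y had 0 against 1957, at a ratio of -10.43 or lower by the limit that a count of 0 allows. The X-escape genes Kdm6a (0.62), Eif2s3x (0.55, 0.38 to 0.72), Ddx3x (0.52) and Kdm5c (0.41) were higher in the female library, and Jpx (0.00) and Ftx (-0.07) were not.

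Among autosomal genes and others outside those lists, Asmt, which encodes an enzyme of melatonin synthesis, had the highest ratio of female over male, 1.51 (1.14 to 1.91). A2m followed with 1.02 (0.94 to 1.09) and Eya4 with 0.90 (0.47 to 1.35). The others among the highest were Sbspon (0.81), Macrod2os2 (0.76), Acss2os (0.64), Tstd2 (0.59), Fgf9 (0.58), Tmem267 (0.58) and Ptger2 (0.57). Higher in the male library were the mitochondrial transcript mt-Atp6, at -1.36 (-1.62 to -1.11), and the myelin genes Mobp, at -1.30 (-1.56 to -1.04), and Mbp (-1.05), with Hbb-bs, a globin gene (-1.27), Ttr, which encodes transthyretin (-1.16), mt-Co3 (-1.09), mt-Co1 (-1.06), Ptgds (-1.06), mt-Nd1 (-1.04) and mt-Cytb (-1.03). Asmt lies on X at 170672644 to 170678054, and Macrod2os2 and Acss2os overlap Macrod2 and Acss2 on the other strand. With the subclusters weighted equally Asmt was at 1.93 and Ptger2 at 0.04, and as a mean over thinned nuclei Asmt was at 2.22, Sbspon at 0.34 and Tmem267 at 1.05.

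**Figure D4:**
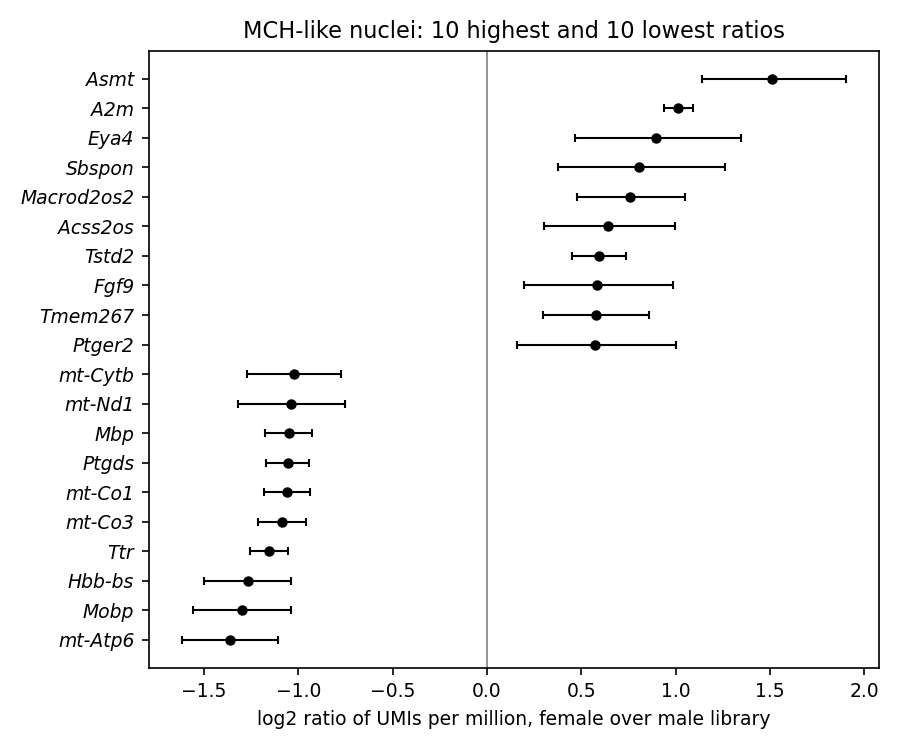
Log2 ratio of female over male summed CPM (horizontal axis) in MCH-like nuclei for the 10 highest and the 10 lowest genes with at least 200 counts, without the Y-linked and X-inactivation lists and 15 predicted or ribosomal genes of like ratios, with 95% intervals covering counting error only. The ratios run from 1.51 for Asmt down to -1.36 for mt-Atp6.

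Over 16481 genes with enough counts the median log2 ratio was -0.03, and 6674 were higher in the female library. The 8 mitochondrial genes had a median of -1.04, at percentile 0 of 10000 random lists of like expression, and the 9 glial transcripts one of -0.86, also at percentile 0, with Slc1a3 at -1.31 and Gja1 at -1.29. The 21 neuropeptide genes had a median of -0.36 (percentile 0), with 3 higher in the female library, and Tac1 (-1.22, -1.82 to -0.63), Npy (-0.97), Penk (-0.81) and Cck (-0.76, -1.07 to -0.44) were among the lower ones. They moved with the mitochondrial and glial transcripts. The 6 stress genes (-0.16, percentile 1.51), the 8 immediate early genes (-0.23, 4.08) and the 15 clock genes (-0.12, 6.41) also lay low, with Hspa5 at -0.29, Jun at -0.60 and Per2 at -0.54 (-0.83 to -0.25), while Fos was at 0.86 (-0.04 to 1.87). The 8 X-linked genes had a median of 0.53 (percentile 100), and the 4 Y-linked genes one of -10.2 (0). In these medians counts under 3 were raised to 3, so the Y-linked median is smaller in size than the ratios of single genes given above would make it.

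The other lists lay inside the range of random lists. Medians and percentiles were 0.07 and 94.5 for the 7 subtype genes, 0.05 and 89.2 for 16 feeding receptors, 0.03 and 87.8 for 24 channel genes, 0.00 and 78.4 for 25 insulin signalling genes, and -0.04 and 57.2 for 26 arousal receptors. They were -0.03 and 50.01 for 6 fast transmitter genes, 0.01 and 46.7 for 20 ionotropic receptors, -0.06 and 44.4 for 7 sex steroid genes, and -0.18 and 16.5 for the 3 orexin genes. Tacr3 was at 0.22, Cartpt at -0.25, Pmch at -0.34 and Trpc6 at 0.39. Hcrtr2 was at 0.70 (0.02 to 1.44), or 1.57 with the subclusters weighted equally, on CPM levels below that of the far shallower male glia. Hcrtr1 was at -0.18 (-0.45 to 0.09) and Hcrt at -0.52 (-0.69 to -0.34).

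The same ratios in other neurons and glia showed which differences lay outside MCH-like nuclei. In other neurons, with cluster 8 the largest in the male and cluster 10 in the female library, the mitochondrial genes had a median of -1.94, the glial transcripts of -2.17 and the neuropeptide genes of -1.13, each at percentile 0. Oxt (-2.83), Hcrt (-2.15, -2.40 to -1.89), Slc17a7 (-3.20) and Tacr3 (-1.55) were lower there in the female library. The subtype genes lay at -0.48 (percentile 0.04), and the arousal receptors at 0.15 (99.6) and ionotropic receptors at 0.16 (99.7). Hcrtr2 was at -0.10 (-0.45 to 0.24) and Hcrtr1 at -0.23. Xist was at 1.93 (1.83 to 2.04), a smaller ratio than in MCH-like nuclei, and male other neurons, of which 5.20% held at least 3 Xist UMIs and no Y-linked UMI, held Xist at 162 CPM and female ones at 617. In glia the mitochondrial genes were at -0.64 (percentile 0.04), the ionotropic receptors at -0.71 (0), the channel genes at -0.57 (0) and the arousal receptors at -1.17 (0.01), whereas the neuropeptide genes were at 0.48 (99.6) with Hcrt at 1.79 (1.25 to 2.32) and Cck at -2.85. Xist was at 3.95 (3.63 to 4.27) in glia.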

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

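Of the tests in this part, those on female nuclei in the male pool and on MCH nuclei mixed into other barcodes were set before their results were seen, and the other tests were chosen after.

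Of 265 genes screened, the named genes of this comparison and the members of the lists, 4 had a difference between MCH-like nuclei and other neurons that went one way in the male library and the other way in the female library. Ramp1, which encodes a subunit of amylin and calcitonin gene-related peptide receptors, had a log2 ratio of MCH-like over other neurons of -0.61 (-0.94 to -0.27) in the male and 0.69 (0.23 to 1.19) in the female library. Foxo1 was at -0.61 (-0.90 to -0.31) and 0.45 (0.13 to 0.79). The kainate receptor gene Grik2 was at 0.037 (0.0024 to 0.073) and -0.068 (-0.098 to -0.038). The potassium channel gene Kcnq3 was at -0.071 (-0.13 to -0.013) and 0.32 (0.27 to 0.38). The reference differed between the libraries, since cluster 8 held 413 of 827 male but 189 of 970 female other neurons, and cluster 10 held 160 and 317. With 1 library per sex these differences between the libraries were not tested.

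A signal outside the comparisons was Xist in the male library: 142 male-library nuclei (2.71%, 2.29 to 3.19) held at least 3 Xist UMIs and no Y-linked UMI, among them 82 MCH-like nuclei (3.47%) and 43 other neurons (5.20%). Free Xist RNA would fall on nuclei with and without Y-linked UMIs alike, and is argued against because 78.9% (142 of 180, 72.2 to 84.6) of male-library nuclei with at least 3 Xist UMIs lacked a Y-linked UMI, against 35.5% of all male-library nuclei, and barcodes shared with the female library are argued against by the 0% of the 142 that shared one. Xist RNA in nuclei of male mice is argued against because 86.3% (82 of 95, 77.7 to 92.5) of male-library MCH-like nuclei with at least 3 Xist UMIs lacked a Y-linked UMI, against 15.1% of all male-library MCH-like nuclei. Nuclei of female mice in the male pool are not argued against and stay open. The median Xist share of the 82 MCH-like nuclei was 120% of that of female-library MCH-like nuclei, but the minimum of 3 UMIs alone fixes 47.8%, so this test decides nothing. Against female-library MCH-like nuclei that also held at least 3 Xist UMIs the medians were alike, at 7.29 and 7.02 per 10000 UMIs. The same minimum raises both medians, so their likeness does not settle the origin of these nuclei. No biological explanation was tested.

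Pmch transcripts were in nearly every analysed nucleus, glia included, although Pmch marks MCH neurons. The median Pmch count of glia and of other neurons differed by at most 1.17 times within a library, but other neurons were defined by a Pmch level of at most 2 times that of glia, so this test decides nothing and free Pmch RNA stays open. MCH nuclei mixed into other barcodes stay open too: for 8 other genes high in MCH-like nuclei the median glial to MCH-like ratio was 22.5% of the Pmch ratio in the female but 58.8% in the male library, where doublets were not removed. The gate on ZsGreen would remove unlabelled glia, which were still present, and no biological explanation was tested.

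Hcrtr2 was lower in MCH-like nuclei than in the other sorted neurons. A difference in depth is argued against by the shares at 2000 UMIs, whose intervals lay at least 1.46 percentage points apart in both libraries, and a few barcodes of very high depth by the log2 fold of -3.86 without nuclei above 40000 UMIs. Free Hcrtr2 RNA, which would reach all droplets of a library alike, is argued against by the Hcrtr2 UMIs per nucleus: the ratio of other neurons over MCH-like nuclei had a lower 95% bound of at least 2.72 in both libraries over the 12 settings with at least 100 MCH-like nuclei, among which the gap of the shares was at least 0.232 percentage points. Glia decide nothing here, since their CPM interval overlapped that of other neurons in 5 of these settings, as in the male library with at least 1000 genes (16.1, 11.9 to 21.3, against 21.7, 17.6 to 26.3) and in the female library clustered alone (20.4, 14.1 to 28.5, against 21.9, 18.2 to 26.3). A lower level of Hcrtr2 transcripts in MCH neurons than in these neurons and reads of the gene on the opposite strand both stay open, the first as a hypothesis found on the same 2 libraries and the second untested.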

How the results depend on the processing

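Of the settings here, the tests with the highest 5% of doublet scores removed, nuclei above 40000 UMIs left out, Pmch UMI classes, clusters with under 3 MCH markers left out, nuclei with Xist left out, the shallow cluster 9 named from its leading markers, subclusters without 1 library, and the levels of Hcrtr1 and Hcrtr2 with 200 genes, resolution 0.5 and libraries clustered alone were chosen after the results were seen. No paired analysis was possible because the male and the female library share only the replicate number 1, given in accession order.

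The MCH-like share of the male and female libraries, 45.1% and 74.2%, was 0.974% and 0.796% with the class made from the Pmch share of UMIs, 22.7% and 62.1% with Pmch UMIs against clusters with Gad2 over 5 times the rest, and 47.9% and 75.9% with Gad2 over 8 times. It was 35.6% and 59.7% without clusters of under 3 MCH markers, 56.5% and 79.7% with at least 1000 genes, and 42.7% and 69.4% with at least 200 genes. In the male library it was 43.6% with the female doublet calls kept, which changed the clusters but not the set of male nuclei. Without the highest 5% of scores it was 43.8%. The Pmch share class held only 51 male and 49 female nuclei, so MCH-like nuclei against other neurons was not run with it. Its limit, 5.07% and 4.47% of UMIs, was set by glia, and Pmch was at 12524 CPM in female glia against 11942 in female MCH-like nuclei (7142 and 15069 in the male library), so this class does not separate MCH nuclei and its values here and below carry little weight. The female share exceeded the male one in all of these but the Pmch share class. Of the shares of 6 other classes 84 stayed within their interval and 54 moved.

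Hcrtr1 was in 1.34% of female and 1.65% of male MCH-like nuclei at 2000 UMIs, 0.679% and 0.890% at 1000, 3.10% and 3.02% at 4000, 6.52% and 6.68% without thinning, and 0% and 0% of the Pmch share class. Hcrtr2, at 0.242% and 0.174%, was at 0.592% in the female library at 4000 UMIs, 0% in the male library at 1000, 1.29% and 0.804% without thinning, and 0% and 0% of the Pmch share class. Fewer or more UMIs per nucleus set these shares by construction. The level of Hcrtr2 in male and female MCH-like nuclei, 1.01 and 1.65 CPM, was 2.70 and 2.26 with Gad2 over 8 times and 0 and 0 in the Pmch share class. That of other neurons, 24.3 and 22.6, was 9.99 and 13.5 with Gad2 over 5 times and 5.71 and 4.22 with the Pmch share class. For male other neurons it was 17.5 with the female doublet calls kept, which changed only the clusters of the same male nuclei. Without the highest 5% of scores it was 18.6. Hcrtr1 in MCH-like nuclei, 7.83 and 6.92, was 5.86 and 5.59 without clusters of under 3 MCH markers and 3.06 in the female Pmch share class. The remaining 41 levels of Hcrtr1 and 34 of Hcrtr2 stayed within their interval.

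Of MCH-like nuclei against other neurons, 3080 genes higher and 3594 lower became 1228 and 1769 with DESeq2, 1077 and 1776 with Gad2 over 5 times, and 1891 and 2106 with thinned nuclei. The fold of Hcrtr2, -3.95, ran from -4.58 to -3.78 without 1 of the libraries and from -4.58 to -2.94 over all 13 alternatives. Hcrt turned to 0.13 with Gad2 over 8 times, Trh to 0.49 with Gad2 over 5 times, Eif2s3y to -0.98 with DESeq2 and Kdm5d to -1.86 without the male library (0.39 without the female one). For the single genes, 822 tested values kept their side of the threshold, and their direction where the reported value passed, 6 newly passed and 60 no longer passed. Of the untested ratios without 1 library 98 stayed within the interval of the reported fold and 64 moved. Without the library in the model 14 genes no longer passed.

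The number of subclusters, 7, was 11 at resolution 0.8. With DESeq2 the genes higher and lower were 391 and 561 in subcluster 1 (1413 and 1483), 391 and 505 in subcluster 2 (1419 and 1443) and 512 and 518 in subcluster 3 (1573 and 1442). Subcluster 2 had 731 and 929 with the second division of the UMIs and 863 higher at resolution 0.8. At that resolution Glra3 turned to -0.41 in subcluster 1 and Ror2 to -0.0061 in subcluster 2. With the second division Hcrtr1 turned to -0.11, Ror2 to -0.46, Ghrh to -0.45 and Slc1a2 to -0.11 in subcluster 2, and Gad2 to -0.12 and Kcnj3 to 0.10 in subcluster 3. Over subclusters 1 to 3, 413, 410 and 437 values of single genes were alike, 8, 7 and 16 newly passed, and 35, 45 and 25 no longer passed. Without 1 of the libraries 118, 129 and 127 ratios stayed within the interval of the fold and 30, 22 and 27 moved, and Tsix, at -0.76 and -0.35 without the male library, turned to 0.23 in subcluster 1 and 0.020 in subcluster 2 without the female one.

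Between the libraries in MCH-like nuclei, the Xist ratio of 4.10 was 6.32 in the Pmch share class, 4.23 with equal weights and 6.33 without nuclei with Xist and no Y-linked UMI. The Hcrtr2 ratio of 0.70 was 1.57 with equal weights. In the Pmch share class Tmem267 turned to -0.82, Foxo1 to -0.23, Gabrg3 to -0.33, Trpc6 to -0.62, Eif2s3x to -0.49, Per3 to 0.60, Hspa5 to 0.59 and Hsp90aa1 to 0.053. With equal weights Foxo1 turned to -0.19 and Grik1 to 0.014, and as a mean over thinned nuclei Glra2 to -0.064. Of the other ratios 502 stayed within their interval and 74 moved. TMM scaling shifted all ratios by 0.04 and size factors by 0.05. With at least 100 counts 12 and with at least 500 counts 7 of the 20 named genes were shared. In other neurons TMM gave 1.961 for Xist and -0.07 for Hcrtr2, and in glia 3.90 for Xist. Clustering at resolution 0.5 or of each library alone was not run for the tests of genes or the ratios between libraries. Except where the construction is named, the cause was not tested.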

Other observations

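No tests were run in this part beyond the subcluster tests, and the genes shown were chosen after their values were seen.

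The neurons sorted with the MCH-like nuclei fell into GABAergic and glutamatergic profiles, over both libraries. Clusters 12 and 16 held Gad2 at 349.97 and 314.98 CPM and Slc32a1 at 76.2 and 63.2, with Slc17a6 at 3.47 and 4.14. Clusters 10 and 14 held Slc17a6 at 93.4 and 115.7 CPM, with Gad2 at 7.46 and 36.2 and Slc32a1 at 0.276 and 1.21. Gad1 ranged from 66.3 CPM in cluster 14 to 180.8 in cluster 12. Cluster 8 held both Gad2 (165.8) and Slc17a6 (67.4), and with them Hcrt (158.6), Oxt (88.3), Sst (59.7), Slc17a7 (25.5) and Sim1 (19.3), and was not split further. Sst, which encodes somatostatin, was also in clusters 12 (51.4) and 16 (122.3), and Scg2 was highest in cluster 10 (217.5). In cluster 14, led by Ano1 and Shroom3, Hcrtr2 was at 31.1 CPM (17.4 to 51.4) in the male and 22.9 (15.1 to 33.4) in the female library, and in cluster 16, led by Ptprt, Otx2os1 and Npsr1, at 8.34 (1.72 to 24.4) and 11.6 (4.65 to 23.8). Hcrtr1 in cluster 16 was at 11.1 (3.03 to 28.5) and 14.9 (6.80 to 28.2).

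Further genes of subclusters 4 to 7 were tested in the same way, with edgeR quasi-likelihood and Benjamini-Hochberg adjusted p. Subcluster 4 was higher in the tachykinin receptor gene Tacr1 (2.16 ± 0.38) and in Bdnf (1.29 ± 0.25) and lower in the serotonin receptor genes Htr4 (-4.71 ± 0.75) and Htr2c (-1.52 ± 0.04). Of its 22 arousal receptors 6 were higher, 9 lower (10 adjusted over the list alone) and 7 did not pass. Subcluster 5 was lower in Foxo1 (-3.29 ± 0.31), Kcnq5 (-3.19 ± 0.08) and Chrm3 (-3.05 ± 0.31) and higher in Trpc5 (1.18 ± 0.04), with 3 arousal receptors higher (4 adjusted over the list alone), 7 lower and 12 not past the test. Subcluster 6 was higher in Foxo1 (1.30 ± 0.15), Penk (1.67 ± 0.40) and Kcnj3 (1.24 ± 0.08) and lower in Ramp1 (-1.87 ± 0.32). Subcluster 7 was higher in Oprk1 (1.82 ± 0.33) and Cnr1 (2.20 ± 0.60). Without the female library Tacr1 was at 3.16 and Htr4, with 1 UMI there, at -3.49 (-8.82 to -0.95) in subcluster 4, Foxo1 at -2.55 and Chrm3, with 2 UMIs, at -4.08 (-7.13 to -2.20) in subcluster 5, Penk at 2.36 in subcluster 6 and Oprk1 at 1.19 in subcluster 7, and without the male library Tacr1 was at 1.48, Foxo1 at -3.88 and Penk at 1.08. Foxo1 ranged from 1.46 CPM (0.301 to 4.27) in subcluster 1 to 74.4 (37.1 to 133) in subcluster 7 of the male library and from 1.40 (0.456 to 3.27) in subcluster 5 to 49.8 (43.1 to 57.3) in subcluster 3 of the female library. For subclusters 4 to 7 no gene values under the alternatives are given besides those without 1 of the libraries. Subcluster 7 had no counterpart with the second division of the UMIs and had leading genes of other neurons, so its place in the MCH-like class is doubtful.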
